A study of Homo sapiens with 24 samples.

How the data were processed

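Total RNA from LNCaP, VCaP, DU145 and PC-3M cells, taken 48 h after transfection with MYB siRNA or NC siRNA, was labelled as biotinylated cRNA and hybridized to Illumina bead arrays of 47231 probes, with 3 arrays per line and siRNA. Per the labels, RNA was extracted with the mirVana kit and labelled with the Illumina TotalPrep kit. The labels state neither the number nor the sequence of the siRNAs, and no slide or scan date. The deposited non-normalized table gives probe signal as intensity on a linear scale, neither background subtracted nor normalized between arrays. The deposited series matrix holds the authors' values in log2, quantile normalized between all arrays. The columns of the matrix had the same sorted values to within 0.002, and the rank correlation of each column with its own array's signals was at least 0.999999.

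The non-normalized signals were the starting point. The deposited table has no detection p-values and no control probes, so background could not be estimated from negative controls. In its place the lowest signal of each array was set to 16, and the arrays were quantile normalized and log2 transformed. A stand-in detection p-value was computed per probe from the mode of each array's signals, with the spread taken from the signals below the mode mirrored about it. A probe was kept where this p-value was under 0.05 on at least 3 arrays, which left 32476 probes. The probe with the highest mean stood for a gene, which gave 24414 genes, 5853 of which had more than 1 kept probe. Names came from a gene table through the Entrez identifier for 18140 genes and through an accession for 22; 6252 kept the file's own name, and 6529 had only a model or clone name. No coordinates were used beyond chromosome names in the gene table. Median signals ranged from 87.34 to 126.2, and the number of arrays limits the precision.

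All 24 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per line and siRNA and no block, with 16 residual and 12.18 prior degrees of freedom, no trend and two-sided moderated tests. The comparisons were MYB siRNA against NC siRNA within each line, the mean of the 4 lines' changes with equal weight, the difference of the changes between lines (a moderated F test, and each pair of lines), and the mean change of LNCaP and VCaP minus that of DU145 and PC-3M. That last comparison sets a pair of lines against another pair, so it measures these lines alone. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 within its comparison.

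The genes named follow a rule set before the data were examined, as were the comparisons, the lists, the fallback for background and the alternatives not stated to be added later. In each line it names MYB and 11 further fixed genes, among them MYBL1, MYBL2, KLK3, TOPBP1, ATR, CHEK1, BRCA1, BRCA2 and PARP1, and the 8 largest falls and 8 largest rises among called genes whose 3 MYB siRNA arrays lay on one side of the 3 NC siRNA arrays and that were above background on all 3 arrays of the higher group. For the mean it names the 10 largest falls and rises with the same sign in all lines, and for differences the 10 smallest F p-values and the 5 largest differences between the pairs of lines on each side. In each list it names up to 4 members with the largest absolute moderated statistic. Genes with a model name only were counted but not named.

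The 21 gene lists, with 627 entries of which 599 were measured, were written from textbook knowledge, none from these samples: ATR and ATM checkpoint signalling; DNA replication; G1/S cyclins, E2F factors and CDK inhibitors; G2/M and mitosis; MYB family and textbook MYB targets; MYC targets in ribosome biogenesis; NF-kB targets and cytokines. The others were RNA interference machinery, apoptosis regulators, cholesterol synthesis, hypoxia and glycolysis, interferon response, p53 targets, the unfolded protein and ATF4 stress response, and markers of epithelial, mesenchymal, neuroendocrine and leukocyte cells. Base excision, mismatch and end-joining repair and homologous recombination and Fanconi anaemia repair were included. The remaining fixed genes and the remaining list are not reported here. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Lists with fewer than 5 measured members were described, not tested.

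The steps were tested on simulated data with the size and layout of this series. In the LNCaP comparison 13 of 67 genes seeded with a log2 change of 0.5 were recovered (19.4%), 56 of 67 with a change of 1 (83.6%) and 66 of 66 with a change of 2, with 8 false calls among 24414 genes. In the mean of the 4 lines 57 of 67 (85.1%), 67 of 67 and 66 of 66 were recovered, with 10 false calls. A simulated list of 40 genes moved by 0.5 was called higher by camera. Of 200 random lists, 10 fell under an unadjusted threshold of 0.05. The simulated noise was independent between genes and had the same spread on every array. Correlated list members and arrays that stand apart were thus not simulated, and these rates need not hold for the real arrays.

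The alternatives were array weights, no background correction, a lowest signal of 50, median scaling, no filter, a stricter filter (p under 0.01 on all 3 arrays of a group), the authors' values, each line fitted alone, every probe on its own, the mean of a gene's probes, trended and robust variances, a fold of at least 1.5, a replicate block over lines or within lines, and leaving out each array in turn. Added after the data were seen were normexp on all probes, leaving out the 3 arrays that stand apart (weight under 0.5), the mean without VCaP, and removal of structural RNA probes. Figures were drawn with matplotlib 3.10.9.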

Results

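Gene expression was measured in 4 human prostate cancer cell lines 48 h after transfection with a small interfering RNA (siRNA) against MYB or with a negative control (NC) siRNA. MYB encodes c-Myb, a DNA-binding transcription factor, and the question was which transcripts respond when it is lowered. The lines were LNCaP, VCaP, DU145 and PC-3M, a metastatic derivative of PC-3. Each line gave 3 Illumina bead arrays per siRNA, 24 arrays in 8 groups. The median probe signal per array ranged from 87.34 to 126.2, and 20353 to 23597 probes per array (43.1% to 50%) were above background. The number of arrays limits the precision. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, some of which can be technical. On average each array correlated with the others of its group at 0.9747 to 0.9927. LNCaP NC siRNA replicate 3, VCaP MYB siRNA replicate 3 and DU145 MYB siRNA replicate 3 stood apart, with estimated array weights of 0.479, 0.299 and 0.405. Changes are log2 differences, MYB siRNA minus NC siRNA, ± the standard error of the fit, with 3 arrays per group, and adjusted p-values cover all 24414 genes tested unless stated.

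The target transcript fell in all 4 lines. MYB, on chromosome 6 and measured by 1 probe (ILMN_1711894), had its largest measured fall in PC-3M, by 2.58 ± 0.15 (adjusted p = 9.65e-12), from a mean log2 level of 9.17 to 6.59. It fell by 1.24 in DU145 (adjusted p = 5.13e-05), by 1.08 in LNCaP (adjusted p = 0.000209) and by 0.94 in VCaP (adjusted p = 0.000102). In each line all 3 MYB siRNA arrays were below all 3 NC siRNA arrays. As a fold, MYB was 2.11-fold lower in LNCaP; in VCaP 1 of the 3 MYB siRNA arrays was above background, and no fold is given. No DU145 MYB siRNA array was above background, so the fold there was at least 1.90. The measured change differed between the lines (adjusted p = 1.17e-05), but the background limits how far a fall can be seen in DU145 and VCaP, so the true falls of these 2 lines cannot be ranked. LNCaP and PC-3M had all arrays above background, and the measured fall was larger in PC-3M (adjusted p = 0.000314 for the difference). The LNCaP MYB siRNA arrays lay only narrowly above it, at log2 levels of 5.92 to 6.22, while a VCaP array not above background was at 5.61. Background may therefore limit the fall and the fold seen in LNCaP too, and this difference does not rank the true falls. In LNCaP the fall held its size but not its call when the line was fitted alone (adjusted p = 0.0552). Without background correction the falls remained called but were smaller near background, -0.67 in LNCaP, -0.51 in VCaP and -0.64 in DU145. A bound written "at least N-fold" is given where no array of the dimmer group was above background, and compares the brighter group's mean with the dimmer group's signals raised to each array's background threshold.

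**Figure D1:**
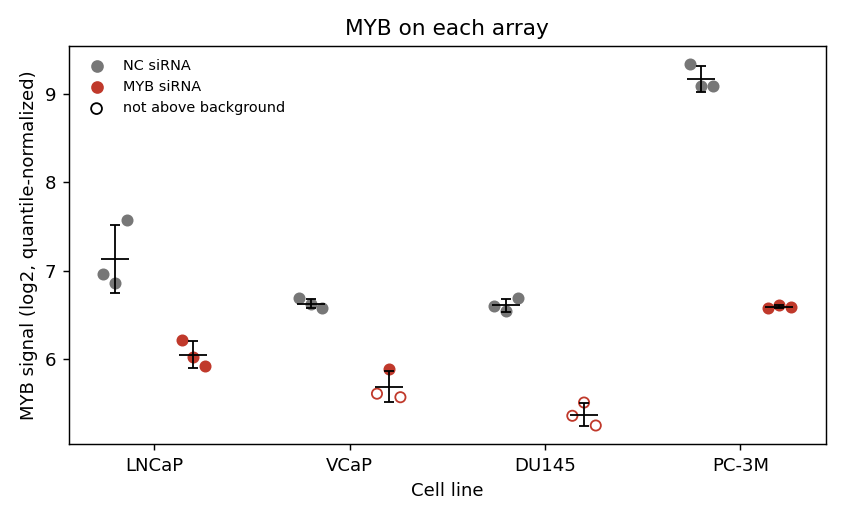
MYB level (log2 signal after quantile normalization) on each of the 24 arrays, by cell line, with NC siRNA in grey and MYB siRNA in red. Open points were not above background and bars give the mean ± SD of 3 arrays; in every line the 3 MYB siRNA arrays lie below the 3 NC siRNA arrays, with the widest gap in PC-3M, where the mean went from 9.17 to 6.59.

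In LNCaP, MYB siRNA raised 142 genes and lowered 37. The largest rise was in ITM2A, a type II membrane protein gene on chromosome X, by 2.10 ± 0.25 (adjusted p = 1.74e-05). NPY, a neuropeptide, rose by 1.64 ± 0.22 (at least 2.13-fold) and ADIRF, an adipogenesis factor, by 1.61 ± 0.20 (at least 2.50-fold). U1 and U4 small nuclear RNA genes rose as well, among them RNU1-3 (2.00 ± 0.31, adjusted p = 0.000742), RNVU1-7 (2.00 ± 0.33) and RNVU1-18 (1.91 ± 0.29). PTPMT1, a mitochondrial phosphatase, rose by 1.32 and TOMM20, a mitochondrial import receptor, by 1.11 (adjusted p = 2.83e-05 and 0.000106). Among the falls, ID1, an inhibitor of basic helix-loop-helix factors, fell by 1.01 ± 0.14 (adjusted p = 9.77e-05), SLC9D1 by 1.07 ± 0.18 (adjusted p = 0.00142) and HEBP1, a heme-binding protein, by 0.87 ± 0.15 (adjusted p = 0.00169). For the largest rises and falls named here and in the other lines, all 3 MYB siRNA arrays lay on one side of the 3 NC siRNA arrays. ITM2A, NPY and ADIRF were abundant in VCaP NC siRNA cells, where the 3 arrays had log2 levels of 13.34 to 13.50 for NPY and 13.81 to 14.06 for ADIRF, and 21 of the 142 genes that rose in LNCaP (14.8%) were at least 4-fold higher in VCaP than in LNCaP under NC siRNA, against 2.74% of all genes.

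None of the 21 gene lists was called in LNCaP by camera, limma's competitive list test; 3 had an unadjusted p under 0.05, and fry, which asks whether members move one way on balance, called 2, leukocyte markers and the RNA interference machinery. Single members changed: CCND3, which encodes cyclin D3, rose by 1.25 (adjusted p = 6.89e-06), E2F2 rose by 0.64 (adjusted p = 0.0199), and RFC5, a subunit of the replication clamp loader, fell by 0.72 (adjusted p = 0.0263). The p53 target SESN1 rose by 0.88 (adjusted p = 0.00328). The replication list had a median of 0.03 while its test leaned lower (adjusted p = 0.743). Hypoxia and glycolysis genes (median 0.16, adjusted p = 0.126) were called higher without LNCaP MYB siRNA replicate 2 (adjusted p = 0.00261), with no filter (0.0357) and under median scaling (0.0124), a scaling that also called the RNA interference machinery (0.0265) higher. KLK3, which encodes prostate-specific antigen, had a change of -0.85 (adjusted p = 0.324). Its log2 level was lower after MYB siRNA at each replicate number, 11.97 to 11.06, 11.65 to 10.85 and 10.74 to 9.90. The fit did not pair replicates, so the missing call does not show that KLK3 was unchanged.

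The LNCaP count depended on single arrays and on the scaling. It was 936 without NC siRNA replicate 3 (515 higher, 421 lower) and 641 without MYB siRNA replicate 1 (321 higher, 320 lower). The excess of rises thus shrank or vanished there. Leaving out NC siRNA replicate 1, NC siRNA replicate 2, MYB siRNA replicate 2 or MYB siRNA replicate 3 gave 109, 53, 77 and 53, most of them higher. Leaving out VCaP MYB siRNA replicate 3 gave 306. NC siRNA replicate 3 correlated less with its own group (0.9825) than with the MYB siRNA group (0.988). Several named genes were not called without LNCaP MYB siRNA replicate 3 (adjusted p): RNU4-1 (1.89; 0.224), RNU4-2 (1.66; 0.0631), EID2 (-1.05; 0.213), PSMC3IP (-1.05; 0.161), LENG9 (-0.95; 0.319) and MOCS2-DT (-0.86; 0.312). The same 6 genes were not called without NC siRNA replicate 2 (0.069 to 0.378). Without MYB siRNA replicate 2, LENG9, MOCS2-DT, PSMC3IP and RNU4-1 were lost (0.0524 to 0.129), as were EID2, MOCS2-DT and PSMC3IP without NC siRNA replicate 1 (0.0661 to 0.0893). Under median scaling 63 genes were called, 62 of them higher, and ID1 had a change of -0.84 (adjusted p = 0.206).

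In the fit of all arrays together VCaP had the most called genes of the 4 lines, 1560 higher and 1432 lower. Enzymes of cholesterol synthesis and their regulators led the rises: HMGCS1 rose by 2.58 ± 0.16 (adjusted p = 3.68e-12), INSIG1 by 2.49 ± 0.15, ACAT2 by 2.39 ± 0.19, DHCR7 by 2.04 ± 0.18, SQLE by 1.96 ± 0.15 and SREBF1, a sterol-responsive transcription factor, by 1.92 ± 0.19. GRIA2, a glutamate receptor subunit, rose by 2.01 ± 0.18, and UHRF1, which maintains DNA methylation, by 2.23 ± 0.19, though the other UHRF1 probe went the opposite way. The largest falls among protein-coding genes were in CEACAM6, an adhesion glycoprotein (-3.05 ± 0.18, adjusted p = 1.18e-12), LGALS3, a galectin (-2.96 ± 0.18), EGLN3, a prolyl hydroxylase (-2.89 ± 0.15), TFF1, a trefoil peptide (-2.87 ± 0.17), CYP1A1, a cytochrome P450 (-2.70 ± 0.20), and TMEM45B (-2.67 ± 0.24). Ribosomal RNA probes fell too, RNA18SN5 with a change of -2.80 ± 0.29 (adjusted p = 8.61e-08) and RNA28SN5 with one of -4.17 ± 0.73 (adjusted p = 0.000211). VCaP MYB siRNA replicate 3 had the lowest RNA28SN5 level, 5.67 against 11.90 and 10.30 on the other MYB siRNA arrays; without it the fall was 2.36. The count of changed genes was 1952 without VCaP NC siRNA replicate 2. Median scaling gave 1185, 896 of them higher. With each line fitted alone, PC-3M had more called genes than VCaP, so that ranking depends on the shared fit.

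As groups, cholesterol synthesis and DNA replication rose furthest in VCaP. Of 25 measured cholesterol genes 18 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 1.55 (adjusted p = 7.9e-29). Of 49 replication genes 32 rose and 1 fell (33 and 2 adjusted over the list alone; median 0.69, adjusted p = 6.15e-24), including the helicase subunit MCM2 (1.85), the flap endonuclease FEN1 (1.69) and the helicase loader CDC45 (1.44, adjusted p = 4.5e-09). Of 38 homologous recombination and Fanconi anaemia genes 15 rose and none fell (16 and 1 adjusted over the list alone; median 0.29, adjusted p = 1.12e-05), with XRCC3 at 1.64 and EXO1 at 1.10. Of 23 ATR and ATM checkpoint genes 7 rose (10 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.000529), among them CDC25A by 1.85 and the checkpoint kinase CHEK1 by 0.99 ± 0.13 (adjusted p = 6.65e-06). Of 34 MYC targets in ribosome biogenesis 12 rose (16 adjusted over the list alone; median 0.36, adjusted p = 3.6e-06), such as RRS1 (1.12) and NCL (0.79). Epithelial markers fell, 7 of 19 (8 and 1 higher adjusted over the list alone; median -0.23, adjusted p = 0.00185), led by KRT19 (-1.72) and GRHL2 (-1.40). These 6 calls held with an estimated correlation between list members. Some member counts moved with 1 array: 8 homologous recombination genes rose without VCaP MYB siRNA replicate 3, 7 ribosome biogenesis genes without NC siRNA replicate 1 and 6 without MYB siRNA replicate 2, and 3 epithelial markers fell without NC siRNA replicate 2.

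Other VCaP lists moved less firmly. Of 25 NF-kB targets 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.0178), with CXCL8, which encodes interleukin 8, down by 2.54 and CXCL1 by 1.02; the list was not called without VCaP NC siRNA replicate 3 (adjusted p = 0.0562) but held with an estimated correlation (adjusted p = 0.0294). In the G2/M list 13 of 58 rose, including AURKB (1.18), and 4 fell, including ECT2 (-1.09), with 13 and 5 adjusted over the list alone (median 0.22, adjusted p = 0.0175). That call was lost without VCaP MYB siRNA replicate 3 (0.137) or NC siRNA replicate 3 (0.0813), with array weights (0.0509) and without the 3 arrays that stand apart (0.128), and adjusted p = 0.351 with an estimated correlation. Without MYB siRNA replicate 3 or NC siRNA replicate 3, 4 and 7 of its members rose. Hypoxia and glycolysis genes were higher, 14 against 3 of 32 (15 and 3 adjusted over the list alone; median 0.32, adjusted p = 0.00185; adjusted p = 0.214 with an estimated correlation), with DDIT4 up by 1.26 and ADM down by 1.36; 7 rose without VCaP MYB siRNA replicate 3 and 9 without NC siRNA replicate 2. Base excision, mismatch and end-joining repair had 5 members higher and 2 lower of 24 (8 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.0132; adjusted p = 0.114 with an estimated correlation; 0.0562 without NC siRNA replicate 3), and 3 higher without MYB siRNA replicate 3. Apoptosis regulators were lower, 6 against 1 of 34 (10 and 5 adjusted over the list alone; median -0.14, adjusted p = 0.0472), with TNFSF10 at -0.93 and XIAP at -0.86, but the median turned to 0.04 (adjusted p = 0.221) under median scaling. That call was lost with an estimated correlation (adjusted p = 0.0966 with an estimated correlation) and without VCaP NC siRNA replicate 3 (0.0974), MYB siRNA replicate 1 (0.0571), MYB siRNA replicate 3 (0.1) or PC-3M NC siRNA replicate 1 (0.0505). It was also lost with no background correction, a lowest signal of 50, the authors' values, the stricter filter, array weights, normexp or without the 3 arrays that stand apart (0.0544 to 0.0911). The interferon list had 1 member higher and 6 lower of 39 (1 and 9 adjusted over the list alone; median -0.04, adjusted p = 0.0485; adjusted p = 0.354 with an estimated correlation), with ISG20 at -1.59. Its adjusted p was 0.05 to 0.227 without any one of LNCaP NC siRNA replicate 2 or MYB siRNA replicate 1, VCaP NC siRNA replicate 3, MYB siRNA replicate 1 or 2, DU145 NC siRNA replicate 1, MYB siRNA replicate 2 or 3, or PC-3M NC siRNA replicate 1 or 2, MYB siRNA replicate 1 or 3; without VCaP MYB siRNA replicate 2 the median was 0.01. The call was also lost with the replicate block within lines (0.0611) or over lines (0.0542), with VCaP fitted alone (0.0853) and under median scaling (0.148).

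The remaining VCaP lists were not called. The G1/S list had 9 members higher, including CDK2 (1.22) and CCNE2 (1.12), and 4 lower, including CDKN1A (-0.93), of 25 (9 and 4 adjusted over the list alone, adjusted p = 0.0506); it was called without LNCaP NC siRNA replicate 1 (0.0445), LNCaP MYB siRNA replicate 3 (0.0488), VCaP NC siRNA replicate 1 (0.0369), NC siRNA replicate 2 (0.0349), MYB siRNA replicate 2 (0.0221) or DU145 MYB siRNA replicate 1 (0.0488), with no filter (0.0246) and under median scaling (0.014). The p53 targets (adjusted p = 0.106) included GDF15, which fell (-2.60). Neuroendocrine markers (adjusted p = 0.162) included SYP, which encodes synaptophysin, up by 0.91. The list of MYB family genes and textbook MYB targets, which holds MYB itself, had 4 of 24 higher and 2 lower (adjusted p = 0.581). The RNA interference machinery had 4 of 13 higher, with a median of -0.19 and a mean of 0.07 (adjusted p = 0.677), among them TNRC6A (1.19). Unfolded protein and ATF4 genes had 6 higher and 2 lower of 31 (adjusted p = 0.289; 0.0331 under median scaling), leukocyte markers 1 higher of 13 (0.581), and mesenchymal markers 1 higher and 2 lower of 18 (0.614). Among the genes fixed in advance, KLK3 fell by 1.15 ± 0.37 (adjusted p = 0.0395) and BRCA1 rose by 0.58 ± 0.18 (adjusted p = 0.0286). KLK3 was -0.39 (adjusted p = 0.459) without VCaP MYB siRNA replicate 3, on which its level was 7.49 against 9.82 and 9.76, and was not called without NC siRNA replicates 1, 2 or 3 (0.0871, 0.0756, 0.117). BRCA1 was not called without MYB siRNA replicates 1 or 3 (0.095, 0.0888) or NC siRNA replicates 1, 2 or 3 (0.0658, 0.0673, 0.0808).

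In DU145, 322 genes rose and 210 fell. PTPMT1 rose by 1.43 ± 0.16 (adjusted p = 1.32e-05), MXD4, a repressor that partners MAX, by 1.40 ± 0.15, the chloride channel gene CLIC3 by 1.39 ± 0.16 and the aspartic protease NAPSA by 1.35 ± 0.17. PIP4K2A (1.36), MSRB3 (1.34), S100A9 (1.26) and the transcription factor NFE2 (1.20, adjusted p = 0.000742) also rose. Beside MYB, the named falls that did not depend on a single array were VPS36, an ESCRT subunit, by 1.34 ± 0.18 (adjusted p = 8.52e-05), and RFC5 by 1.21 ± 0.16 (adjusted p = 7.89e-05). The cyclin gene CCND1 fell by 0.94 and its kinase partner CDK6 by 0.65. Without DU145 MYB siRNA replicate 3, the falls of CHORDC1 (-1.30), NDUFAF4 (-1.22), RRP15 (-1.11), NPM1P21 (-1.10) and ZBTB8OSP2 (-1.14) were not called (adjusted p 0.0581 to 0.299). All but RRP15 were also lost without NC siRNA replicate 2 (0.0595 to 0.117), NPM1P21 and ZBTB8OSP2 without NC siRNA replicate 1 (0.0646 and 0.154), and CHORDC1, NPM1P21 and ZBTB8OSP2 without NC siRNA replicate 3 (0.0522 to 0.0622). The count of changed genes was 156 without MYB siRNA replicate 3, and 278, 174 and 235 without NC siRNA replicates 1, 2 and 3. Median scaling turned the balance, with 11 genes higher and 429 lower. Of the fixed genes, CHEK1 had a change of -0.47 (adjusted p = 0.0593) and BRCA2 one of -0.56 (adjusted p = 0.052), and neither passed. CHEK1 was called without LNCaP NC siRNA replicate 1 (0.0397) or DU145 MYB siRNA replicate 1 (0.0443), and BRCA2 without VCaP MYB siRNA replicates 1, 2 or 3 (0.0403, 0.0442, 0.0427) or DU145 MYB siRNA replicate 1 (0.0277).

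Genes of ribosome biogenesis, DNA repair and replication were lower as groups in DU145. MYC targets in ribosome biogenesis had 6 of 34 members lower (12 adjusted over the list alone; median -0.34, adjusted p = 4.87e-12), including DKC1, the pseudouridine synthase, at -0.83. Homologous recombination and Fanconi genes had 3 of 38 lower (14 adjusted over the list alone; median -0.33, adjusted p = 5.09e-10). Replication had 8 of 49 lower (11 adjusted over the list alone; median -0.22, adjusted p = 1.04e-08), and the checkpoint list 2 of 23 (4 adjusted over the list alone; median -0.13, adjusted p = 0.00432), with TIPIN at -0.92. The G2/M list was lower with no single gene past the threshold (5 adjusted over the list alone; median -0.24, adjusted p = 6.56e-07; adjusted p = 0.0622 with an estimated correlation). Base excision, mismatch and end-joining repair had 1 of 24 lower (6 adjusted over the list alone; median -0.24, adjusted p = 0.00161; adjusted p = 0.0513 with an estimated correlation). NF-kB targets were lower (1 of 25, CXCL8 at -0.95; 4 lower and 1 higher adjusted over the list alone; median -0.14, adjusted p = 0.0334; adjusted p = 0.0513 with an estimated correlation), a call lost without MYB siRNA replicate 2 (0.111) or NC siRNA replicate 3 (0.0681) and with the stricter filter (0.0548). Cholesterol synthesis was higher, with 4 of 25 members passing (6 adjusted over the list alone; median 0.20, adjusted p = 3.17e-06), but median scaling, which moved the median of all DU145 genes by -0.139, gave -0.17 (adjusted p = 0.538), or -0.04 relative to that shift. Hypoxia and glycolysis genes were higher too, 3 of 32, with PGM1 at 0.98 and NDRG1 at 0.84 (4 adjusted over the list alone; median 0.08, adjusted p = 0.00701; adjusted p = 0.361 with an estimated correlation), and that scaling turned the median to -0.18 (adjusted p = 0.874), or -0.05 relative to the shift. With an estimated correlation 5 calls held, those of ribosome biogenesis, homologous recombination, replication, checkpoint and cholesterol genes. The counts of single members rested on few arrays. Without DU145 MYB siRNA replicate 3, the array that stands apart, 1 member each passed in the replication, ribosome biogenesis, checkpoint and homologous recombination lists and 0 in the cholesterol and base excision lists. Without NC siRNA replicates 1, 2 and 3, replication had 4, 2 and 5, ribosome biogenesis 2 each time and homologous recombination 1, 0 and 0; the checkpoint list had 1 without NC siRNA replicates 1 or 2. Cholesterol had 1 without NC siRNA replicates 2 or 3 and 2 without MYB siRNA replicate 2, base excision 0 without NC siRNA replicate 1 and 2 without MYB siRNA replicates 1 or 2, and homologous recombination 0 without MYB siRNA replicate 2 and 5 and 6 without VCaP MYB siRNA replicates 2 and 3. NF-kB had 2 without DU145 MYB siRNA replicate 1, LNCaP NC siRNA replicate 3, VCaP MYB siRNA replicates 1 or 3 or PC-3M NC siRNA replicate 1. Apart from the NF-kB list, each of these lists stayed called with any 1 array left out. No other list was called (adjusted p 0.323 to 0.973), though median scaling called the G1/S list (-0.31, adjusted p = 0.00172) and apoptosis regulators (-0.42, adjusted p = 0.00656) lower and neuroendocrine markers (0.07, adjusted p = 0.0245) higher. In 2 of these the signs were mixed: the RNA interference list had a median of 0.15 and a test that leaned lower, and p53 targets a median of 0.07 and a mean of -0.00.

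In PC-3M, 591 genes rose and 608 fell. MSMP, a secreted microseminoprotein, rose by 2.53 ± 0.19 (adjusted p = 9.35e-10), UTS2, the urotensin peptide gene, by 2.20 ± 0.17, KCNK12, a potassium channel gene, by 2.01 ± 0.17 and HPGD, which breaks down prostaglandins, by 1.93 ± 0.16. FABP4 rose by 1.73 ± 0.18, TOMM20 by 1.73 ± 0.15, DYNLT3 by 1.71 ± 0.16 and PTPMT1 by 1.69 ± 0.16. Beside MYB, RFC5 fell most, by 1.92 ± 0.16 (adjusted p = 8.3e-09), followed by ID3 (-1.74 ± 0.16), the dihydrofolate reductase pseudogene DHFRP2 (-1.53 ± 0.15), DTL, a ubiquitin ligase substrate receptor of replicating cells (-1.51 ± 0.17), the bromodomain ATPase ATAD2 (-1.42 ± 0.21), EXO1 (-1.42 ± 0.17) and BTG3 (-1.41 ± 0.15). Of the fixed genes, MYBL1, a MYB paralogue, fell by 0.96 ± 0.17 (adjusted p = 0.000465), TOPBP1, an activator of ATR, by 0.92 ± 0.20 (adjusted p = 0.00444), CHEK1 by 0.82 ± 0.13 (adjusted p = 0.000193) and BRCA1 by 0.78 ± 0.18 (adjusted p = 0.00564). BRCA2 fell by 0.61 ± 0.16 (at least 1.32-fold, adjusted p = 0.0172), a call lost without MYB siRNA replicates 2 or 3 (0.124, 0.0565) or NC siRNA replicates 1 or 2 (0.0777, 0.137). The count of changed genes was 717 without MYB siRNA replicate 3, and 793 and 786 without NC siRNA replicates 1 and 2. Median scaling gave 475.

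The cell cycle and DNA repair lists fell together in PC-3M. In the G2/M list 49 of 58 members fell and none rose (54 adjusted over the list alone; median -0.82, adjusted p = 5.02e-57), including ANLN (-1.31), CCNA2 (-1.12) and MELK (-1.11). Of 49 replication genes 28 fell (35 adjusted over the list alone; median -0.68, adjusted p = 3.11e-36), including MCM10 (-1.31) and GINS2 (-1.21). Of 38 homologous recombination and Fanconi genes 20 fell (26 adjusted over the list alone; median -0.56, adjusted p = 1e-21), among them RAD51AP1 (-1.22). Of 23 checkpoint genes 8 fell (12, with 1 higher, adjusted over the list alone; median -0.51, adjusted p = 4.91e-08). In the G1/S list 7 of 25 fell, including CCND1 (-0.97) and SKP2 (-0.84), and the CDK inhibitor gene CDKN2B rose by 0.96 (10 lower and 3 higher adjusted over the list alone; median -0.23, adjusted p = 3.72e-05). Base excision, mismatch and end-joining repair had 6 lower and 1 higher of 24 (8 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.000452), led by MSH6 (-1.20) and POLQ (-1.11). The MYB target list had 5 lower, MYB among them, and 2 higher of 24 (7 and 2 adjusted over the list alone; median -0.17, adjusted p = 0.00127), with NMU at -0.84 and the survival factor MCL1 at 0.98. Cholesterol synthesis rose, 7 of 25 (11 adjusted over the list alone; median 0.37, adjusted p = 4.11e-08), with LSS at 1.03 and HMGCS1 at 0.86. These calls held with an estimated correlation; hypoxia and glycolysis, with 8 of 32 higher (8 and 1 lower adjusted over the list alone; median 0.20, adjusted p = 2.26e-06), did not (adjusted p = 0.0712 with an estimated correlation). DDIT4 (1.27) and CA9 (1.04) were among its rises. Without PC-3M NC siRNA replicate 2 or MYB siRNA replicate 3, 4 cholesterol and 5 hypoxia genes rose; 5 checkpoint genes fell without MYB siRNA replicates 1 or 3, 3 base excision genes without MYB siRNA replicate 2 and 3 MYB targets without NC siRNA replicate 1. NF-kB targets (adjusted p = 0.175), p53 targets (0.21) and MYC targets (0.767) were not called.

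**Figure D2:**
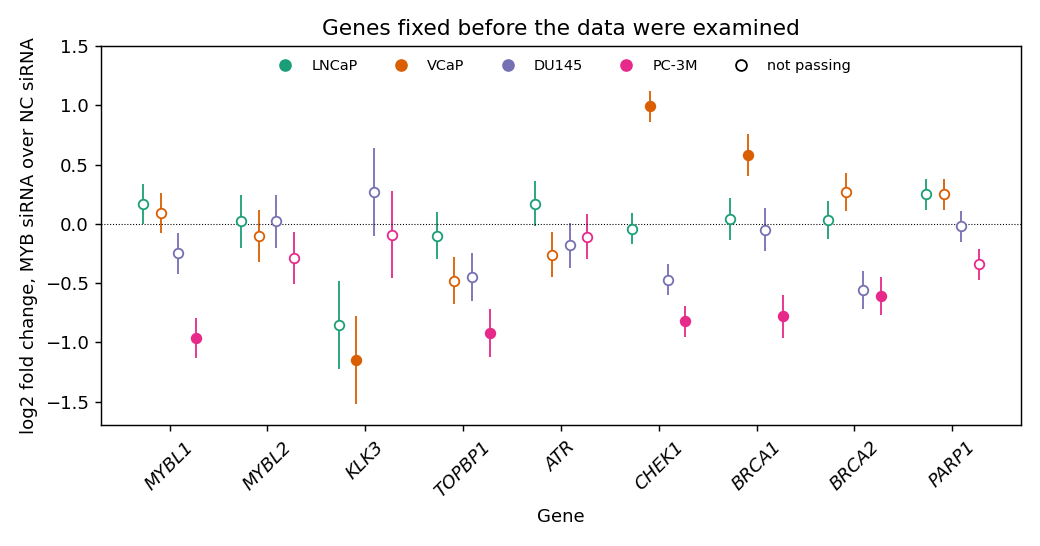
Log2 change (MYB siRNA minus NC siRNA) ± standard error of genes fixed before the data were examined, in each line, with 3 arrays per siRNA. Filled points passed an adjusted p of 0.05; CHEK1 was higher in VCaP (0.99) and lower in PC-3M (-0.82).

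Averaged over the 4 lines with equal weight, 1206 genes rose and 929 fell, of which 743 and 513 had the same sign in every line. HMGCS1 (1.17 ± 0.08, adjusted p = 1.94e-10) and INSIG1 (1.01 ± 0.07) rose most with PTPMT1 (1.12 ± 0.08) and TOMM20 (1.01 ± 0.08), but these 4 genes changed unevenly: PTPMT1 rose by 1.32, 1.43 and 1.69 in LNCaP, DU145 and PC-3M and had a change of 0.04 in VCaP (adjusted p = 4.05e-05 for the difference between lines). CALU, which encodes a calcium-binding protein of the endoplasmic reticulum, rose by 0.93 ± 0.10 (adjusted p = 3.56e-07), with 0.98, 0.75, 0.96 and 1.05 in LNCaP, VCaP, DU145 and PC-3M. The stress granule gene G3BP2 rose by 0.85 ± 0.07. Beside MYB (-1.46 ± 0.08), KRT80, an epithelial keratin, fell by 1.00 ± 0.07 (adjusted p = 4.27e-10), with -2.61 in VCaP, and TMEM30A, a flippase subunit, by 0.94 ± 0.09 (adjusted p = 2.41e-08). TOPBP1 fell by 0.49 ± 0.10 (adjusted p = 0.00192); MYB aside, no other fixed gene reported passed in the mean with all arrays. BRCA2 (-0.22, adjusted p = 0.0819) was called without VCaP MYB siRNA replicate 1 (0.0326), DU145 MYB siRNA replicate 1 (0.0462) or PC-3M NC siRNA replicate 3 (0.0488), MYBL1 (-0.24, adjusted p = 0.0829) without LNCaP NC siRNA replicate 2 (0.0263) or DU145 MYB siRNA replicate 1 (0.0459), and KLK3 (-0.46, adjusted p = 0.138) without VCaP MYB siRNA replicate 1 (0.0432). CYP1A1 (-0.87 ± 0.10) fell mainly in VCaP: without that line its mean was -0.26 (adjusted p = 0.22). With median scaling 568 genes passed in place of 2135.

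Cholesterol synthesis rose in the mean, with 18 of 25 members higher and none lower over all genes and adjusted over the list alone (median 0.52, adjusted p = 4.58e-27). The G2/M list fell, 23 of 58 (31, with 1 higher, adjusted over the list alone; median -0.23, adjusted p = 5.1e-16), as did homologous recombination and Fanconi genes, 6 of 38 (8 adjusted over the list alone; median -0.10, adjusted p = 9.45e-06). Hypoxia and glycolysis genes rose, 13 against 2 of 32 (19 and 3 adjusted over the list alone; median 0.20, adjusted p = 5.16e-08), and NF-kB targets fell, 4 of 25 (5 adjusted over the list alone; median -0.07, adjusted p = 0.0205), with CXCL8 at -1.06 and CXCL1 at -0.55. Without VCaP the NF-kB list was not called (-0.05, adjusted p = 0.125). The p53 list was called lower (5 against 3 of 29; 6 and 3 adjusted over the list alone; median -0.06, adjusted p = 0.0368), a call lost with the replicate block within lines (0.0528), with the stricter filter (0.0721), without VCaP (0.214) and without any one of LNCaP NC siRNA replicate 3 (0.0523), LNCaP MYB siRNA replicate 1 (0.0733), VCaP NC siRNA replicate 2 (0.0599), VCaP MYB siRNA replicate 1 (0.051), DU145 NC siRNA replicate 2 (0.0558), DU145 MYB siRNA replicate 1 (0.0506) or PC-3M NC siRNA replicate 1 (0.0549). These 6 lists kept their calls with an estimated correlation. Replication genes had 4 members higher and 7 lower of 49 in the mean (median -0.04, adjusted p = 0.0756), and a median of -0.28 (adjusted p = 9.54e-23) over the 3 lines other than VCaP. The list was called lower in the mean of the 4 lines under several settings: no background correction (0.0357), a lowest signal of 50 (0.0454), median scaling (0.00746), the authors' values (0.0368), no filter (0.0495), the mean of a gene's probes (0.0115), array weights (0.0349) and without the 3 arrays that stand apart (0.0232). It was also called without LNCaP MYB siRNA replicate 3 (0.0325), VCaP MYB siRNA replicate 3 (0.0409) or PC-3M MYB siRNA replicate 2 (0.0461). Apoptosis regulators (median -0.04, adjusted p = 0.0597) were called lower with no background correction (0.0479), the authors' values (0.0479), no filter (0.0351), median scaling (0.0184) and the mean of a gene's probes (0.0115). They were also called without LNCaP NC siRNA replicate 1 (0.0354), LNCaP MYB siRNA replicate 3 (0.0325), VCaP MYB siRNA replicate 2 (0.0437), DU145 MYB siRNA replicate 2 (0.0473) or PC-3M MYB siRNA replicate 2 (0.0449). The checkpoint list (median -0.04, adjusted p = 0.0819) was called lower under median scaling (0.0206), with the mean of a gene's probes (0.0234), with array weights (0.0428), without LNCaP MYB siRNA replicate 3 (0.0385) and without VCaP (-0.20, adjusted p = 6.07e-07). Without VCaP the G1/S (-0.14, adjusted p = 0.0069), ribosome biogenesis (-0.13, adjusted p = 0.0016) and base excision lists (-0.06, adjusted p = 0.0016) were called lower too, and the G1/S list also under median scaling (0.0423). Of the lists not called, medians and means had opposite signs for MYB targets (0.06 and -0.04, adjusted p = 0.589) and unfolded protein genes (-0.02 and 0.03, adjusted p = 0.862).

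The response differed between the lines for 2604 genes, and the average response of LNCaP and VCaP differed from that of DU145 and PC-3M for 1354. EGLN3 had the smallest p-value of the difference (adjusted p = 2.02e-10), with -2.89 in VCaP and 0.14, 0.09 and -0.07 in LNCaP, DU145 and PC-3M. CEACAM6, FOXQ1 and EMP1 also fell most in VCaP (-3.05, -2.38 and -2.31). GDF15, a stress cytokine, had -2.60 in VCaP and 0.68 in PC-3M (adjusted p = 1.17e-09), the last a call lost without PC-3M MYB siRNA replicates 1 or 3 (0.0786, 0.102) or NC siRNA replicate 2 (0.115). KCNK12 fell by 1.44 in VCaP and rose by 2.01 in PC-3M (adjusted p = 1.42e-09). CDC45 and FEN1 had -0.06 and 0.02 in LNCaP, 1.44 and 1.69 in VCaP, and -1.02 and -1.05 in PC-3M (adjusted p = 1.17e-09 and 6.37e-09). Between these pairs of lines, MCM10 (1.75 ± 0.16, adjusted p = 1.65e-07), DTL (1.68 ± 0.17), EXO1 (1.64 ± 0.17), ATAD2 (1.62 ± 0.21) and GINS2 (1.61 ± 0.15) had a higher mean change over LNCaP and VCaP, and the histone genes H2AC6 (-2.08 ± 0.43, adjusted p = 0.00277) and H2AC18 (-1.85 ± 0.31), TMEM45B (-1.87 ± 0.24), the actin-severing protein gene GSN (-1.75 ± 0.19) and KCNK12 (-1.67 ± 0.17) lower. Among the fixed genes CHEK1 (1.12, adjusted p = 4.64e-06), MYBL1 (0.74), BRCA1 (0.73), and BRCA2 (0.73) differed between the pairs. So did the measured change of MYB (0.90), which background limits in DU145 and VCaP and may limit in LNCaP. PARP1 (0.43, adjusted p = 0.0404) lost its call (0.0529 to 0.0835) without any one of 15 arrays, LNCaP NC siRNA replicate 2 or MYB siRNA replicates 2 or 3, VCaP NC siRNA replicates 1 or 3 or MYB siRNA replicate 3, any DU145 array but MYB siRNA replicate 3, or PC-3M NC siRNA replicates 1 or 2 or MYB siRNA replicates 2 or 3. KLK3 (-1.09, adjusted p = 0.0845) was called without LNCaP NC siRNA replicate 3 (0.0318), VCaP MYB siRNA replicate 1 (0.0259) or VCaP MYB siRNA replicate 2 (0.0303).

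Replication and mitosis separated the lines. In LNCaP and VCaP against DU145 and PC-3M, 31 of 49 replication genes were higher and none lower (39 and 1 adjusted over the list alone; median 0.87, adjusted p = 4.49e-42), and 30 of 58 G2/M genes were higher (48 adjusted over the list alone; median 0.59, adjusted p = 9.01e-30). Homologous recombination and Fanconi genes had 21 of 38 higher (26 adjusted over the list alone; median 0.57, adjusted p = 5.4e-21). Cholesterol synthesis had 11 higher and 1 lower of 25 (13 and 1 adjusted over the list alone; median 0.45, adjusted p = 7.8e-07). Epithelial markers were lower (4 of 19, with KRT19 at -1.31; 7 adjusted over the list alone; median -0.22, adjusted p = 0.00123), but median scaling, which moved the median of all genes in this difference by 0.137, turned their median to 0.06 (adjusted p = 0.0531), or -0.08 relative to that shift. These 5 calls held with an estimated correlation. The pairs held unlike lines: the cholesterol response of LNCaP was below that of PC-3M (median difference -0.29, adjusted p = 0.000764), and between LNCaP and VCaP the replication list differed by a median of -0.78 (adjusted p = 2.44e-20), and between VCaP and PC-3M by 1.49 (adjusted p = 2.86e-47), with 33 of 49 members higher in VCaP's response. Between DU145 and PC-3M the G2/M list differed by 0.62 (adjusted p = 3.15e-29), and cholesterol synthesis was not called (adjusted p = 0.38).

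**Figure D3:**
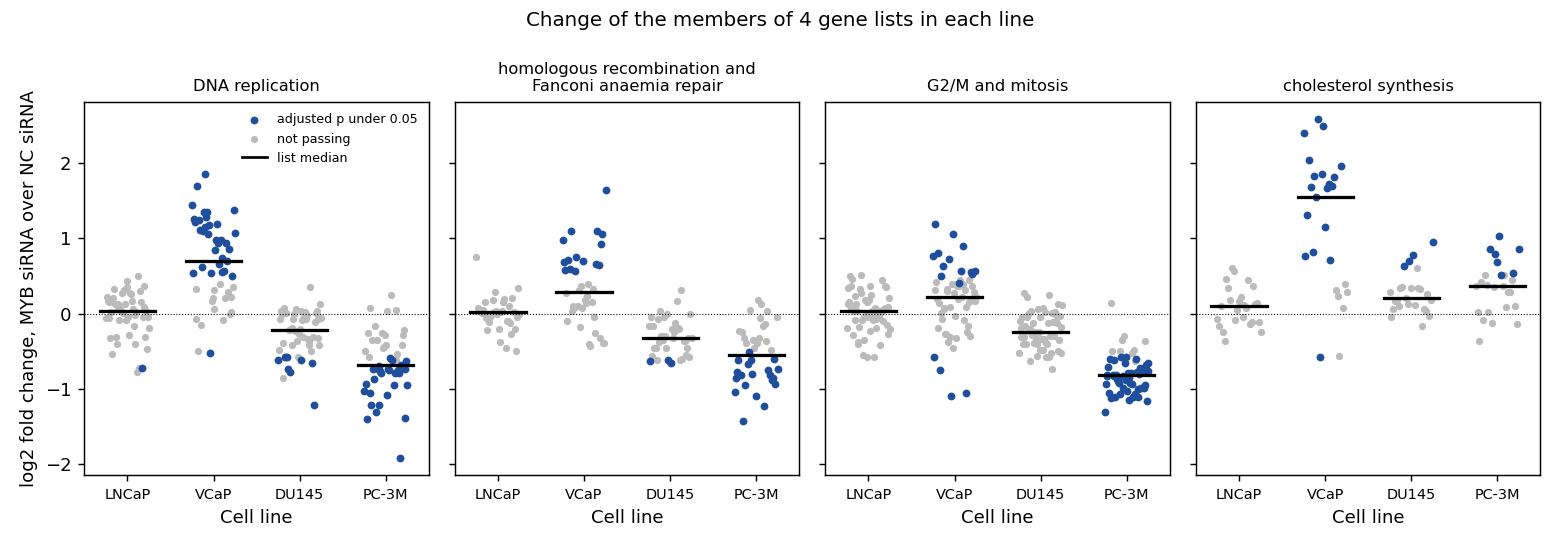
Log2 change (MYB siRNA minus NC siRNA) of each measured member of the lists shown, by line, with the list median as a black line and members past an adjusted p of 0.05 in blue. The replication median was 0.69 in VCaP and -0.68 in PC-3M, and the cholesterol median was 1.55 in VCaP.

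Of the 6 pairs of lines, DU145 and PC-3M shared the most rises, 133 genes, where independent calls would share 7.79. They shared 74 falls (5.23 if independent), beside 75 in VCaP and PC-3M. Overlaps were counted on quantile-normalized values only. Under median scaling few DU145 genes were called higher, so most of the rises shared with PC-3M would not be called. LNCaP and DU145 shared 31 rises (1.87 if independent) and 6 falls (0.318). Across genes, which are not independent replicates, the changes in DU145 and PC-3M had a Spearman correlation of 0.29; the other 5 pairs of lines had -0.01 to 0.14. VCaP and PC-3M shared 80 rises (37.8 if independent) and 75 falls (35.7), but 144 genes rose in VCaP and fell in PC-3M (38.8). In all 4 lines 5 genes rose, CALU, G3BP2, FAM217B, GSE1 and PPP3CB, and 2 fell, MYB and TMEM30A; these names follow from the small counts and were chosen after their values were seen. FAM217B rose by 0.97, 0.69, 0.60 and 1.02 in LNCaP, VCaP, DU145 and PC-3M. Several of these calls rest on single arrays. In LNCaP, CALU was not called without MYB siRNA replicates 2 or 3 (0.0641, 0.124) or NC siRNA replicates 1 or 2 (0.099, 0.0671), G3BP2 without MYB siRNA replicates 2 or 3 (0.188, 0.164) or NC siRNA replicates 2 or 3 (0.144, 0.0534), and TMEM30A without MYB siRNA replicate 3 (0.203) or NC siRNA replicate 1 (0.064). CALU was not called in VCaP without VCaP MYB siRNA replicate 3 (0.134), and in DU145 neither CALU nor G3BP2 was called without MYB siRNA replicate 3 (0.0808, 0.0504) or NC siRNA replicate 2 (0.0634 for each). The lines share no control arrays.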

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

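Several tests were chosen only after the results they concern were seen. These were the tests of VCaP RNA without a limit on level, of swapped VCaP labels and of the quantile normalization. The tests of a response that differs between lines and of off-target action were so too. For the other tests the predictions were written beforehand. Those on ITM2A, structural RNA and the VCaP array that stands apart still concern patterns found in these data. The removal of structural RNA probes was itself added after the data were seen. Differences between the lines drew attention here, each by a test of the difference itself: 2604 genes differed in their response over the 4 lines, and for 1354 the mean response of LNCaP and VCaP differed from that of DU145 and PC-3M. In 100 drawn splits of the arrays within lines, only the real labels gave as many genes, in 1 split each, against a highest other of 2366 between the lines and 1086 between these pairs of lines, so chance labelling can be excluded. Those highest splits kept VCaP and PC-3M as labelled.

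Among the genes fixed in advance the response differed over the lines for MYB (adjusted p = 1.17e-05), CHEK1 (8.22e-07), BRCA1 (0.00343), MYBL1 (0.00526) and BRCA2 (0.0117). For MYB, background limits the falls seen in DU145 and VCaP and may limit the fall seen in LNCaP. The mean response over LNCaP and VCaP was higher than that over DU145 and PC-3M for DNA replication (adjusted p = 4.49e-42), G2/M (9.01e-30), homologous recombination and Fanconi anaemia repair (5.4e-21), MYC targets in ribosome biogenesis (3.79e-08), checkpoint signalling (6.22e-08), cholesterol synthesis (7.8e-07), base excision, mismatch and end-joining repair (1.75e-06), the G1/S list (0.00123) and the MYB target list (0.00326). For cholesterol synthesis VCaP alone was above the other pair: the response of LNCaP was below that of PC-3M (median difference -0.29, adjusted p = 0.000764). The mean response was lower for epithelial markers (adjusted p = 0.00123), but median scaling turned their median to 0.06 (adjusted p = 0.0531).

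The first pattern weighed is that replication genes rose in VCaP and fell in PC-3M (adjusted p = 2.86e-47 for the difference). Swapped VCaP labels are argued against by MYB, whose change of -0.94 in VCaP has the sign the labels give. The VCaP array that stands apart is argued against as the whole cause by a VCaP list median of 0.67 without it, and the quantile normalization by a median of 0.86 under median scaling. Without structural RNA probes the median was 0.69, as with them. Their removal moved no list and no count of changed genes beyond 1.5 times. A removal that moves so little cannot decide whether loss of ribosomal RNA signal entered the normalization, so this stays open. It reaches the normalization only, and any other effect of that loss stays open too. A response to MYB that differs between the lines stays open, because the design confounds the line with its cultures and with any unequal effect of the siRNAs, which cannot be told apart.

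The second pattern is the set of genes that rose in LNCaP, led by ITM2A. Structural RNA carried into labelling is argued against for the set as a whole, since 7 of the 142 genes were ribosomal, small nuclear or small nucleolar RNA. It stays open for those 7, as such genes were 227 of all 24414. Of the 37 genes that fell, 2 were of these classes too. A trace of VCaP RNA in the LNCaP MYB siRNA samples may account for ITM2A, NPY and ADIRF and stays open. The test left out NPY and ADIRF because they were named rises, so REG4 was the only gene left. REG4 implied shares of 0.19%, -0.0384% and -0.0349% on MYB siRNA replicates 1, 2 and 3, where ITM2A implied 1.98%, 0.726% and 0.334%. Over the same replicates the log2 levels of NPY (7.65, 6.47 and 6.22) and ADIRF (7.78, 6.69 and 6.57) fell in the order of the ITM2A shares. Over 5237 genes at background in LNCaP, the signal gained grew with the VCaP level beyond 2 standard errors on MYB siRNA replicates 1 and 2. The slopes were 0.477 ± 0.047% and 0.164 ± 0.05% of that level. Replicate 3 lay at the limit (0.10 ± 0.05%), and the control array NC siRNA replicate 3 was itself beyond it (0.091 ± 0.041%). The rule therefore does not set replicate 3 apart from a control, and its standard errors treat genes as independent. Slopes of the MYB siRNA arrays on the DU145 and PC-3M levels were -0.068 to 0.035%. A shift of LNCaP cells toward genes that VCaP expresses would give such slopes as well, so neither is settled.

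The third pattern is the 43 genes higher and 21 lower in at least 3 lines, MYB among the latter. Off-target action of the siRNAs could give shared changes that do not follow how far MYB fell, and the median absolute change of these genes without MYB was 0.94 in PC-3M and 0.79 in DU145, a ratio of 1.19. It was 0.63 in LNCaP and 0.53 in VCaP, but background limits the MYB falls seen in DU145 and VCaP, so in these 2 lines the sizes cannot be set against MYB's true fall. LNCaP and PC-3M were above background, LNCaP only narrowly. PC-3M had both the larger MYB change (-2.58 against -1.08) and the larger shared changes, but this is 1 pair of lines that differ in other ways. The genes were also chosen by calls in at least 3 lines, and PC-3M had 1199 calls against 179 in LNCaP. Genes such as DDIT4 (0.01 in LNCaP, 1.27 in PC-3M) entered without a change in LNCaP. The choice thus shapes these sizes and the ratio, which decide nothing on the cause. The labels describe neither the siRNAs nor a rescue, so a response to MYB and off-target action cannot be told apart.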

How the results depend on the processing

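Normexp on all probes, leaving out the 3 arrays that stand apart, the mean without VCaP and the removal of structural RNA probes were chosen after seeing the data. Over all alternatives, 243 of the counts of changed genes stayed within 1.5 times the reported one and 41 did not; of the single genes' values 15070 kept direction and side of the threshold, 323 lost the call, 185 gained it and 2 reversed; of the lists' 4791 kept both, 51 lost the call and 51 gained it. MYB fell under every alternative in all 4 lines; its call was lost once, in LNCaP fitted alone (-1.08, adjusted p = 0.0552). Replicate numbers did not pair the samples in most cases: 2 of 12 pairs had a correlation above 0.1 (-0.13 to 0.29). Both were in LNCaP, replicate 1 at 0.11 and replicate 3 at 0.29, and the 3 arrays that stand apart are all replicate 3. An effect tied to the replicate number is therefore not excluded. With a replicate block over lines the counts were 221 in LNCaP, 3250 in VCaP, 690 in DU145 and 1316 in PC-3M, each above the count reported. A block on slide was not run, since no slide is given. Signals near background limit the folds of weak genes such as MYB in DU145.

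The LNCaP count, 179 as reported, was 307 with no background correction, 287 with a lowest signal of 50, 306 with the authors' values, 285 with normexp, 270 with the replicate block within lines (160 higher), 63 with median scaling (62 higher), 25 for the line alone (24 higher), 851 with array weights and 1802 without the 3 arrays. That last figure rests on arrays left out because of their spread and is no stronger evidence. The DU145 count, 532, was 920, 862, 918 and 834 with the first 4 of these settings, 817 with array weights, 318 alone and 339 without the 3 arrays; median scaling gave 440, 11 of them higher. The VCaP count, 2992, was 1185 with median scaling (75.6% higher, against 52.1%) and 1243 alone. The PC-3M count, 1199, was 475 with median scaling, 2720 with array weights, 2148 alone and 1869 without the 3 arrays. The mean count, 2135, was 568 with median scaling and 158 with a fold of at least 1.5, which asks more of each gene. The count that differs between lines, 2604, was 1298 with median scaling and 3942 without the 3 arrays; that between LNCaP and VCaP and the other pair, 1354, was 1833 with median scaling, 94.2% of them higher against 58.7%. Without VCaP the mean turned from a fall to 0.056 for EGLN3 (adjusted p = 0.811) and 0.20 for GDF15 (adjusted p = 0.269), whose falls were in VCaP. Otherwise the cause was not tested.

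With 1 array left out the count ranged from 53 (without LNCaP NC siRNA replicate 2 or MYB siRNA replicate 3) to 936 (without NC siRNA replicate 3) in LNCaP, from 1952 (without VCaP NC siRNA replicate 2) to 3406 in VCaP, from 156 (without DU145 MYB siRNA replicate 3) to 767 in DU145 and from 717 (without PC-3M MYB siRNA replicate 3) to 1476 in PC-3M. It ranged from 1639 to 2545 for the mean, 1956 to 3298 between lines and 1051 to 1600 between the pairs of lines.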

Other observations

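Targets of bone morphogenetic protein (BMP) signalling other than ID1 and ID3 were lower in VCaP, where 7 of 8 measured members fell (median -0.91, adjusted p = 2.17e-10; adjusted p = 0.0012 with an estimated correlation). SMAD9, a BMP signal transducer, fell by 2.09, the BMP decoy receptor gene BAMBI by 1.96, ID4 by 1.05 and ID2 by 0.92. Histone cluster genes other than H2AC6 and H2AC18 were higher in PC-3M, 10 against 1 of 59 (median 0.15), with H2AC19 up by 1.38 and H4C8 by 1.19. In LNCaP the histone list was lower (median -0.10, adjusted p = 3.86e-05; adjusted p = 0.0369 with an estimated correlation), and in VCaP it was not called (adjusted p = 0.199). These lists were written after the named genes were seen and form a family of 12 tests.

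A first hypothesis was that the falls of ID1 in LNCaP and ID3 in PC-3M may reflect lower BMP signalling. The other BMP targets were not called in LNCaP (median -0.21, adjusted p = 0.062) or in PC-3M (median -0.04, adjusted p = 0.119), which leaves it open for these lines; the fall in VCaP was not part of the prediction.

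Another hypothesis was that histone transcripts, which lose their usual non-polyadenylated form when replication stops, may have risen in PC-3M as replication genes fell. The histone list was higher there (adjusted p = 8.5e-05), but borderline with an estimated correlation (adjusted p = 0.041). Its members are histone cluster genes, as are H2AC6 and H2AC18, which prompted the test. The test was therefore not free of the values that prompted it. In DU145, where replication genes were lower as well, it was not called (median 0.06, adjusted p = 0.0544; adjusted p = 0.272 with an estimated correlation). It is a hypothesis found and tested on the same data, and polyadenylation was not measured.

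A further hypothesis was that the fall of CYP1A1 in VCaP may follow from lower aryl hydrocarbon receptor activity. Of the other targets 4 were measured, too few to test as a list, and 3 were lower, NQO1 (-1.60), CYP1B1 (-0.76) and TIPARP (-0.69).

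Other splits of the 6 arrays of a line into 3 against 3 number 10, the real one included, too few for a share under 0.05. In VCaP, DU145 and PC-3M the real labels gave 2992, 532 and 1199 genes and the highest other split 84, 0 and 0, so 1 split in each line gave as many. In LNCaP 2 splits gave as many as the real 179. The other, NC siRNA replicates 1 and 2 with MYB siRNA replicate 1 against the rest, gave 480. A grouping other than by siRNA thus gave more genes in these samples, for a cause that was not tested. For the mean of the 4 lines, 1 of 100 drawn splits, the real one, gave as many as 2135 genes, and the highest other gave 835, so chance labelling can be excluded there.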
